A study of Mus musculus with 6 samples.

How the data were processed

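RNA was measured in 6 libraries of MC3T3-E1, a mouse pre-osteoblastic cell line. Per the labels, 3 libraries came from cells given a plasmid with the EGFP gene (control 1 to 3) and 3 from cells given a plasmid with Hsd11b1 (overexpression 1 to 3). All 6 had been incubated with 11-DHC (11-dehydrocorticosterone), the inert steroid that the enzyme encoded by Hsd11b1 turns into corticosterone. Total RNA was isolated with TRIzol and made into libraries with a stranded mRNA kit. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples.

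The submitters' processing notes name cutadapt 2.5, HISAT2 2.1.0, featureCounts 1.6.3 and the mouse build mm10. The annotation release, the strand setting of the counting and the tool behind the authors' differential test are not given in the sources used here. The values used are FPKM (fragments scaled by exon length and by library total), which the authors deposited for each library in a table of 15796 genes. The authors' deposited table also holds a log2 fold change, a p-value and an adjusted p-value per gene, and a second table holds the 310 of these genes at a fold change of at least 2 and p under 0.05. The authors' values were used only for a comparison of counts and for the fold change of Hsd11b1.

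Read numbers were recovered from the FPKM to measure depth. For 15776 genes a length was taken as the union of exons in GENCODE M21 (build GRCm38, the same as mm10), and the total that turned the products of FPKM and length into whole numbers was sought for each library. Of the values at or below 1000 reads, 93.7% to 94.9% per library were whole within 0.05 reads. In all 6 libraries, 14389 genes (91.1%) were whole, within 0.05 reads or, for genes with any value above 1000 reads, within 0.2 reads. On simulated libraries, 6 of 6 totals were recovered within 0.1%.

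The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(FPKM + 1) of the 13120 genes with a mean FPKM of at least 1 over the 6 libraries. It compared 3 overexpression with 3 control libraries, with no covariate. Tests were two-sided, and p-values were adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05. A second count took genes with a log2 difference of at least 1 in size and an unadjusted p under 0.05. Differences are overexpression minus control and carry the standard error (SE) of the fit, while FPKM means carry the standard deviation (SD). Adding 1 to the FPKM makes the log2 difference of low genes smaller than that of their means. For Hsd11b1, an exact two-sided permutation test was also run.

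A total of 24 gene lists were fixed, named below and in the results by pathway or cell type: glucocorticoid-induced, glucocorticoid-repressed inflammatory, osteoblast, osteocyte, collagen and bone matrix, Wnt, BMP and TGF-beta, osteoclast coupling, glycolysis, insulin and IGF, TCA cycle and oxidative phosphorylation, mitochondrially encoded, adipogenic, cell cycle, unfolded protein response, interferon, immediate early, steroid, p53 and apoptosis, Notch, chondrocyte, skeletal muscle, macrophage and endothelial genes. The 20 lists with at least 5 tested members were tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the 20 lists. Tested members were also counted at the gene threshold over all genes and with p-values adjusted over the list alone. Counts out of a list refer to its tested members unless its full size is stated. The samples, lists, tests, thresholds and first set of alternative settings were chosen before the data were examined, and so was the rule for naming genes. The rule takes Hsd11b1, the 10 genes with the smallest p in each direction without predicted genes and pseudogenes (1 skipped among the higher genes, 0 among the lower), and of each list up to 4 members with the smallest p and 2 with the highest FPKM. Other members are named where 5 or fewer of a list passed, or as examples, and were chosen after their values were seen. A branch of the plan for raw read counts was not used, since the values are FPKM. For 3 further lists (acute-phase proteins, the circadian clock and cholesterol synthesis), the genes were written after the results had been seen.

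On simulated libraries with the depths of these 6 and 200 changed genes among 11882, limma recovered 81.5% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1 or 2. Of 186 calls, 9 (4.8%) were unchanged genes. The simulated genes varied independently, with the same spread between replicates for all of them. In the real libraries, deviations followed GC content across genes (below), so these shares need not hold for the real calls.

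That set held pseudocounts of 0.1 and 5, no filter and a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, limma without a trend, a replicate block, limma's arrayWeights, each library left out in turn, camera with an estimated correlation, and fry, which tests whether the genes of a list move on balance 1 way. Chosen after the data were seen were voom on the recovered reads, reads thinned to the shallowest library, a fit without the 2 deepest libraries, no filter for the 3 further lists, and the steroid list without Hsd11b1. Copies of Gapdh were found with BLAST 2.17.0 at 98% identity or more over at least 300 bases. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.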

Results

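Gene expression was measured by RNA sequencing in MC3T3-E1 pre-osteoblastic cells transfected with an Hsd11b1 plasmid (3 libraries) or an EGFP plasmid (3 libraries), all incubated with 11-DHC. Recovered totals were 19932493, 34948121 and 16264240 reads in control 1 to 3 and 18290824, 18655715 and 58665308 in overexpression 1 to 3. Control 2 and overexpression 3 were thus the deepest of their groups. Between libraries of 1 group, Pearson's r of log2 FPKM across genes, which are not independent replicates, was 0.988 to 0.992 for the controls and 0.991 to 0.994 for overexpression. The first principal component held 55.6% of the variance and separated the groups, and the next held 19.5% and put control 2 (-11.8) and overexpression 3 (-10.4) on 1 side, with control 3 at -2.3 and the other libraries at 5.9 or above.

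The single comparison asks how 11β-HSD1, the enzyme that regenerates active glucocorticoid inside cells, regulates bone formation and glucose handling in osteoblastic cells under glucocorticoid excess. Hsd11b1 (ENSMUSG00000016194, chromosome 1, 193221634 to 193264075, GRCm38) had an FPKM of 0.860 ± 0.903 (SD, n = 3) in controls and 328 ± 15.1 (SD, n = 3) with overexpression. Its recovered reads numbered 161, 60 and 19 in the control libraries and 25141, 25019 and 85931 in the overexpression libraries. The log2 difference was 7.57 (SE 0.27, limma adjusted p = 1.86e-06), and the authors' deposited table gives a log2 fold change of 8.58. The exact two-sided permutation test over 20 assignments gave p = 0.1, the smallest that 3 against 3 can give. Reads from the plasmid and from the cells' own gene were not told apart.

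Among 13120 genes tested, 816 were higher and 766 lower with Hsd11b1 overexpression. The genes with the smallest p among the higher ones included Lcn2, which encodes the secreted protein lipocalin 2, Fkbp5, a co-chaperone of the glucocorticoid receptor, and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper. Fkbp5 rose from an FPKM of 21.1 ± 0.207 to 96.0 ± 2.51 (4.56-fold, adjusted p = 6.28e-07) and Tsc22d3 from 49.9 ± 1.72 to 186 ± 1.53 (3.73-fold, adjusted p = 1.71e-06; SD, n = 3, limma). Lcn2 rose from 0.110 ± 0.106, with 1 control library at 0, to 12.3 ± 0.571 (log2 difference 3.58, SE 0.09). Actn3, an alpha-actinin, rose from 1.23 to 16.9 (13.71-fold), and Tns1, which encodes the adhesion protein tensin 1, from 3.86 to 25.7 (6.65-fold). The receptor tyrosine kinase gene Mertk rose from 5.19 to 24.7 and Gdpd2 from 2.41 to 12.4. The retinaldehyde dehydrogenase gene Aldh1a1 rose from 2.25 to 19.0 and its close paralog Aldh1a7 from 2.89 to 27.0. Reads can be shared between these paralogs.

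**Figure D1:**
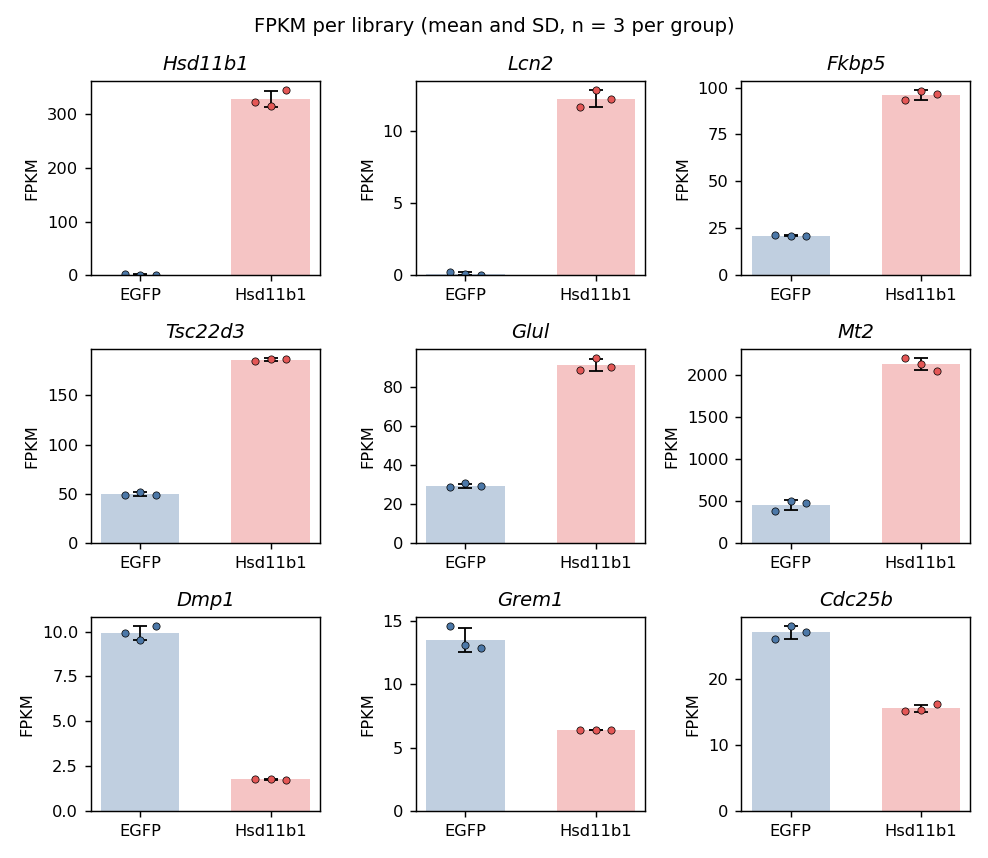
FPKM (vertical axis, from 0) of 9 genes in the control (EGFP) and overexpression (Hsd11b1) libraries. Points are single libraries, bars are means and error bars are SD with n = 3 per group; for Dmp1, the overexpression mean was 1.77 and the control mean 9.93.

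Dmp1, a matrix protein gene of osteocytes and mineralizing osteoblasts, had the smallest p among lower genes and fell from an FPKM of 9.93 ± 0.394 to 1.77 ± 0.017 (SD, n = 3), with a log2 difference of -1.98 (SE 0.07, adjusted p = 1.71e-06). The extracellular matrix gene Spon2 fell from 16.8 ± 1.84 to 5.98 ± 0.204, the chemokine gene Cx3cl1 from 22.2 ± 1.22 to 9.42 ± 0.926, and Grem1, which encodes a secreted BMP antagonist, from 13.5 ± 0.945 to 6.36 ± 0.017. The growth factor gene Ptn fell from 62.1 to 34.5, and Nov, a CCN family matrix protein gene, from 51.2 to 26.2. Cdc25b, a phosphatase that activates cyclin-dependent kinases, fell from 27.1 to 15.5, and the proliferation-associated genes Pclaf and Nusap1 fell by 0.83 and 0.76 on the log2 scale. Afap1l2 fell from 14.4 to 7.59. These 9 higher and 10 lower genes kept their direction and call in each alternative in which they were tested, at least 16 for every gene.

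**Figure D2:**
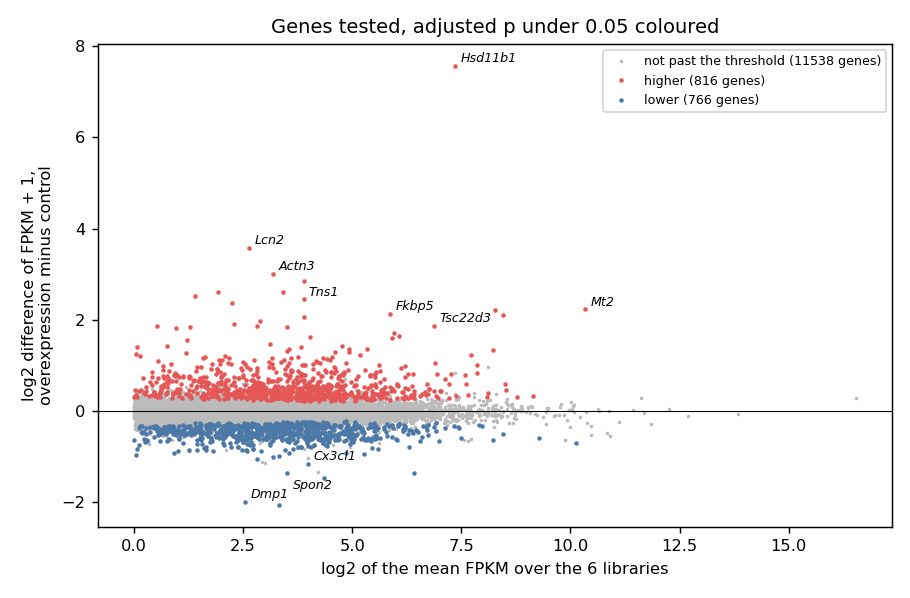
Log2 difference of FPKM + 1 (overexpression minus control, vertical axis) against the log2 of the mean FPKM (horizontal axis) for the 13120 genes tested. Each point is a gene, with 816 higher genes in red, 766 lower genes in blue and the others in grey; Hsd11b1 lies at 7.57 and Dmp1 at -1.98.

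At a 2-fold change and an unadjusted p under 0.05, 82 genes were higher and 10 lower. With a pseudocount of 0.1 these became 128 and 34, and with 5 they became 34 and 5. Leaving out 1 library gave 74 to 84 higher and 11 to 16 lower genes. At the adjusted threshold, the higher genes numbered 483 without overexpression 2. The lower genes numbered 412 without overexpression 2, 464 without overexpression 1 and 484 without control 3. With arrayWeights, 1357 genes were higher and 1403 lower. Without the 2 deepest libraries, a fit chosen after the data were seen, 1071 genes passed, of which 974 were among the 1582 called with all 6. The authors' deposited table calls 1065 genes higher and 1005 lower at an adjusted p under 0.05, and 1459 of the 1582 genes called here pass there in the same direction. The authors' 2-fold table has 246 higher and 64 lower genes, of which 67 have an adjusted p of 0.05 or above there. Of the 310, 138 had a mean FPKM under 1 and were not tested here, and 168 of the 172 tested were called in the same direction.

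Glucocorticoid-induced genes rose together. Of 25 members, 20 were tested. Angptl4 and Cdkn1c were not listed, and Zbtb16, Fam107a and Hif3a had a mean FPKM under 1. Of the 20 tested, 18 rose and 0 fell, and the same numbers held adjusted over the list alone. Lcn2, Sult1a1 and Rgs2 had control means under 1 (0.110, 0.856 and 0.804). They passed the filter only through the overexpression libraries. The kinase gene Sgk1 rose from an FPKM of 32.2 to 102 (log2 difference 1.64, SE 0.07), and Glul, which encodes glutamine synthetase, from 29.5 ± 1.02 to 91.4 ± 3.14. The metallothionein genes Mt1 and Mt2 rose from 132 to 570 and from 454 to 2129, where reads can be shared between the pair. Cdkn1a (0.14, adjusted p = 0.394) and Tgm2 (0.10, adjusted p = 0.529) did not pass. The median log2 difference was 1.30 (camera adjusted p = 1.69e-28), and the call held with an estimated correlation (adjusted p = 0.0413). The 18 members rose with each library left out, and 17 rose without the 2 deepest.

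Osteoblast differentiation genes divided. Of 21 members, 11 were tested. Alpl, Bglap, Enpp1 and Phospho1 were among those not listed, and Ibsp, Pth1r, Msx2 and Ifitm5 had a mean FPKM under 1. Of the 11 tested, 4 fell, 2 rose and 5 did not pass, and adjusted over the list alone 6 fell and 2 rose. These counts do not cover the untested members. Besides Dmp1, the pyrophosphate transporter gene Ank fell from 39.0 ± 1.58 to 25.8 ± 0.268, Tnfrsf11b, which encodes the RANKL decoy osteoprotegerin, from 23.1 ± 1.11 to 15.1 ± 1.53, and the cadherin gene Cdh11 from 81.0 to 65.6. The osteoblast transcription factor genes Dlx5 and Runx2 rose by 0.33 and 0.25 on the log2 scale. Spp1 (osteopontin) had 1251 in controls and 1142 with overexpression (adjusted p = 0.446). The list was lower (median -0.30, camera adjusted p = 0.00979), with adjusted p = 0.230 with an estimated correlation, and adjusted p = 0.105 with no filter on low values. The call of Runx2 ended with each library left out (adjusted p 0.0585 to 0.168), that of Dlx5 without overexpression 1 or 3 (up to 0.0748), and that of Cdh11 with any but control 2 (up to 0.0877). Without the 2 deepest libraries, 4 members fell and 0 rose.

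Osteocyte markers numbered 6 tested, of which Dmp1 fell and Irx5 (0.44) and Capg (0.44) rose; adjusted over the list alone 3 rose and 2 fell. Their median was 0.093, their mean -0.211 and camera's direction up (adjusted p = 0.862), while fry gave lower (adjusted p = 0.000456). Irx5 lost its call without overexpression 2 (adjusted p = 0.0558), and Capg without overexpression 2 or control 3 (up to 0.0662). Among collagen and bone matrix genes, 7 of 29 rose, 2 fell and 20 did not pass, against 10 and 5 adjusted over the list alone. Lox, the enzyme that cross-links collagen, rose from 126 ± 6.14 to 297 ± 16.8, and Postn (periostin) from 171 ± 20.8 to 430 ± 37.0. Col6a2 rose from 118 to 178, and the proteoglycan gene Lum fell from 7.88 to 3.92. The other lower member, P4ha1, fell by 0.32 on the log2 scale and lost its call without overexpression 1 or 2 (adjusted p up to 0.0768). Col1a1, the main bone collagen gene, had 767 and 632 (adjusted p = 0.175), and Fn1 832 and 921 (adjusted p = 0.433). The matrix list did not pass camera (adjusted p = 0.220) but was higher under fry (adjusted p = 0.0152). With control 1, control 3, overexpression 1 or overexpression 2 left out, 4 matrix members rose.

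BMP and TGF-beta genes were higher as a list (median 0.15, camera adjusted p = 0.00455), with adjusted p = 0.157 with an estimated correlation. Of 27 members, 21 were tested, while Bmp2 and Nog were among those not listed. Of the 21 tested, 8 rose, 2 fell and 11 did not pass. Adjusted over the list alone 9 rose and 2 fell. The BMP target genes Id3 and Id4 rose from 11.2 to 24.8 and from 51.9 to 78.4. Besides Grem1, Tgfb3 fell by 0.26 on the log2 scale and lost its call with any library but control 1 left out (adjusted p up to 0.163). Of 32 Wnt members, 15 were tested. Sost, Dkk1, Sfrp1, Wif1 and Notum were among those not listed, and Lef1 and Tcf7 had a mean FPKM under 1. Of the 15 tested, 3 rose, 3 fell and 9 did not pass, the same adjusted over the list alone. The co-receptor gene Lrp5 rose from 19.8 to 36.7, Axin2, a feedback target of the pathway, from 0.860 to 2.07 and Ctnnb1 (beta-catenin) from 99.1 to 136, while the secreted Wnt modulator Sfrp2 fell from 11.0 to 6.40. Wnt5a and Wisp1 fell by 0.27 and 0.30 on the log2 scale, and Wnt5a lost its call with each library left out (adjusted p 0.0757 to 0.142), Wisp1 with any but control 2 (up to 0.124). The list's median was -0.075 (-0.140 without control 1 and -0.049 without control 3), its mean 0.022 and camera's direction down (adjusted p = 0.862).

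Of 14 osteoclast coupling factors, 8 were tested. The RANKL gene Tnfsf11, Il11, Sema4d, Wnt16 and Cthrc1 were not listed, and Il6 had a mean FPKM under 1. Of the 8 tested, Tnfrsf11b, Ccl2 and Wnt5a fell, Efnb2 rose by 0.35 and 4 did not pass. The same counts held adjusted over the list alone (camera adjusted p = 0.488). Efnb2 lost its call with any library but overexpression 1 left out (adjusted p up to 0.137), and Ccl2 without control 1 or 3 or overexpression 1 or 3 (up to 0.0708), while Wnt5a lost it with each library left out. Of 12 Notch members, 6 were tested, while Hey1, Hey2, Heyl and Nrarp were among those not listed. The receptor gene Notch1 rose by 0.39, its target Hes1 fell by 0.56 and 4 did not pass (camera adjusted p = 0.220). Adjusted over the list alone, 2 rose and 1 fell. Notch1 lost its call without overexpression 2 (adjusted p = 0.0560), and Hes1 without overexpression 1 or 2 (up to 0.0540).

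Glucose uptake and glycolysis genes were lower as a list (median -0.18, camera adjusted p = 0.00160), but the adjusted p = 0.403 with an estimated correlation, and 0.0605 under fry. Of 25 members, 20 were tested. The glucose transporter genes Slc2a3 and Slc2a4 and the aldolase genes Aldoa and Aldoc were not listed, and Slc16a3 had a mean FPKM under 1. Of the 20 tested, 4 fell, 0 rose and 16 did not pass, and 7 fell adjusted over the list alone. The lactate and pyruvate carrier gene Slc16a1 fell from 15.7 ± 0.979 to 11.1 ± 0.836, and lactate dehydrogenase gene Ldha from 263 ± 17.1 to 213 ± 8.31. Tpi1 fell from 279 to 223, while Pgk1 (419 and 351, adjusted p = 0.0859) and Pgam1 (354 and 331, adjusted p = 0.584) did not pass. Gapdh fell from 30.8 ± 13.8 to 10.4 ± 4.44, and 16 listed copies of it at 98% identity or more held 72932 reads against 15010 for the gene itself. Ldha and Tpi1 lost their calls with each library left out (adjusted p up to 0.161 and 0.168), and Gapdh without control 1 or 2 or overexpression 1 or 2 (up to 0.0863), so 1 to 2 members fell. Without the 2 deepest libraries, 1 member fell, and without control 2 the list's median was -0.111. With arrayWeights 8 members fell, and with voom on recovered reads 6.

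Insulin and IGF signalling genes included 3 that rose, 0 that fell and 19 that did not pass (camera adjusted p = 0.176); adjusted over the list alone, 6 rose and 2 fell. Igfbp5, an IGF-binding protein, rose from 2.40 ± 0.369 to 4.93 ± 0.407, Pik3r1, a regulatory subunit of PI3-kinase, from 17.0 to 25.1, and Foxo3 from 24.0 to 29.8. The adaptor gene Irs1 had 12.8 and 10.5 (adjusted p = 0.0507). Foxo3 lost its call without overexpression 1 or 2 (adjusted p up to 0.0629). Of 26 tested TCA cycle and oxidative phosphorylation genes, Idh2, a mitochondrial isocitrate dehydrogenase, rose from 55.6 to 98.4. Cycs (cytochrome c) fell from 39.6 to 30.9 and 24 did not pass (camera adjusted p = 0.297). Adjusted over the list alone, 1 rose and 0 fell. Cycs lost its call with any library but control 3 left out (adjusted p up to 0.123). Mitochondrially encoded transcripts were lower as a list (median -0.35, camera adjusted p = 0.00638), with adjusted p = 0.404 with an estimated correlation and 0.112 under fry. Of 12 tested members, 11 did not pass, all with negative differences. Only mt-Nd6 fell past the threshold (1382 to 848), as it did adjusted over the list alone. Its call ended with any library but control 2 left out (adjusted p up to 0.106), and without overexpression 3 the list's median was -0.211. Their share of all FPKM was 4.5%, 4.0% and 5.4% in control 1 to 3 and 4.1%, 3.8% and 3.0% in overexpression 1 to 3. In the same sum, 4 abundant noncoding genes held 29.9%, 27.8% and 24.1% in the controls. They held 30.6%, 32.5% and 28.7% in overexpression 1 to 3. Mean FPKM of the mitochondrial members ran from 2.36 (mt-Nd4l) to 6624 (mt-Co1), and whether reads of the low members were left uncounted was not tested.

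Cell cycle genes fell together. Of 30 members, 29 fell and 0 rose, the same adjusted over the list alone. The DNA topoisomerase gene Top2a fell from 56.5 ± 6.19 to 31.6 ± 0.825, Birc5 (survivin) from 26.4 to 15.5, the mitotic cyclin gene Ccnb1 from 20.6 to 13.2 and the replication helicase gene Mcm4 from 26.7 to 17.0. The G1 cyclin genes Ccnd1 and Ccnd2 fell from 140 to 103 and from 116 to 77.8. The median was -0.55 (camera adjusted p = 6.93e-23), and the call held with an estimated correlation (adjusted p = 0.0413). Leaving out 1 library gave 26 to 29 lower members.

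Among p53 and apoptosis genes, Sesn1 rose from 20.5 to 39.4, the survival gene Bcl2l1 rose from 16.9 to 31.2, Bcl2 fell from 1.33 to 0.863 and 11 of 14 did not pass (camera adjusted p = 0.185, and 0.0108, higher, under fry). Adjusted over the list alone, 3 rose and 1 fell, and Bcl2 lost its call with each library left out (adjusted p 0.0657 to 0.157). Of 15 tested immediate early genes, Egr1 (8.50 to 4.69), Egr2 (8.06 to 3.98), Fosl1 and Klf4 fell. Jund rose and 10 did not pass (camera adjusted p = 0.378). Adjusted over the list alone, 3 rose and 4 fell. Fosl1, Klf4 and Jund lost their calls without 3, 5 and 4 of the libraries in turn (adjusted p up to 0.0594, 0.149 and 0.0864), among them control 3 and overexpression 2 for all of these genes. Unfolded protein and amino acid response genes were higher as a list (median 0.12, camera adjusted p = 0.00979), with adjusted p = 0.403 with an estimated correlation, 0.0734 without control 3 (median 0.08), 0.0616 at a mean FPKM of at least 5 and 0.0605 under fry. Vldlr (2.52 to 5.35), the amino acid transporter gene Slc7a5 (42.2 to 58.2) and the pseudokinase gene Trib3 (9.31 to 13.0) rose, 0 of 21 fell and 18 did not pass, as also adjusted over the list alone. The chaperone gene Hspa5 had 144 and 157 (adjusted p = 0.402).

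Inflammatory genes listed as repressed by glucocorticoids were higher as a list (median 0.22, camera adjusted p = 0.00680), with adjusted p = 0.403 with an estimated correlation. Of 22 members, 12 were tested. Tnf, Cxcl1, Cxcl2, Mmp3 and Nos2 were among those not listed, and Il6 and Icam1 had a mean FPKM under 1. Of the 12 tested, 5 rose, 2 fell and 5 did not pass, and adjusted over the list alone 7 rose and 3 fell. These counts do not cover the untested members. Il1rl1, the receptor for interleukin 33, rose from 22.3 ± 2.63 to 58.7 ± 4.86, the chemokine gene Ccl5 from 5.54 to 11.6 and the collagenase gene Mmp13 from 4.62 to 8.72. Tnfaip3, an inhibitor of NF-kB signalling, rose from 5.30 to 8.62, and Cxcl12 from 9.92 to 13.6. Ccl2 and Vcam1 fell by 0.36 and 0.33 on the log2 scale, and both lost their calls without control 1 or 3 or overexpression 1 or 3, and Vcam1 also without overexpression 2 (adjusted p up to 0.0708 and 0.0768). Interferon response genes were higher (median 0.26, camera adjusted p = 1.37e-07), with adjusted p = 0.403 with an estimated correlation and 0.0634 under fry. Of 26 tested members, 8 rose, 0 fell and 18 did not pass, and 13 rose adjusted over the list alone. Oasl1 rose from 1.47 to 2.73, the signal transducer Stat2 from 83.4 to 109, and the antiviral genes Mx1 and Mx2 from 19.4 to 32.3 and from 14.0 to 20.7. Bst2 had 199 and 246 (adjusted p = 0.116). Leaving out 1 library gave 1 (without overexpression 2) to 10 higher interferon members, with 2 without overexpression 1 and 2 without control 3, and 9 rose without the 2 deepest libraries.

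Steroid metabolism and receptor genes did not pass as a list (median 0.016, camera adjusted p = 0.226), which holds the transfected Hsd11b1 itself. The list passed as higher under fry (adjusted p = 0.00544) and at a mean FPKM of at least 5 (0.0279). Without Hsd11b1, a setting chosen after the data were seen, the median was -0.004, and the list did not pass camera (adjusted p = 0.656) or fry (0.0534). At a mean FPKM of at least 5 without Hsd11b1, it did not pass camera (0.166) and passed as higher under fry (0.00729). With Hsd11b1, the median ran from -0.048 (without control 2) to 0.060 (without overexpression 3), was 0.005 without control 1, and was -0.044 and -0.021 without overexpression 1 and 2. Of 21 members, 15 were tested, of which 4 rose, 2 fell and 9 did not pass, with 4 and 3 adjusted over the list alone. Besides Hsd11b1, H6pd, which supplies the cofactor of 11β-HSD1 in the endoplasmic reticulum, rose from 8.04 ± 0.525 to 14.6 ± 0.958, the vitamin D receptor gene Vdr from 9.31 ± 0.050 to 18.0 ± 0.914, and Hsd17b11 from 14.4 to 21.9. Nr3c1, the glucocorticoid receptor gene, fell from 21.3 to 16.7 and Cyp7b1 from 3.18 to 2.15. Nr3c1 lost its call with any library but control 2 left out and Cyp7b1 with any but control 1 (adjusted p up to 0.111 and 0.128). Of 19 adipogenic genes, 9 were tested. Pparg, Cebpa, Adipoq, Lpl and Plin1 were among those not listed, and Fabp4 had a mean FPKM under 1. Among the 9 tested, Cebpb rose from 18.4 ± 3.56 to 39.1 ± 5.89. Of the others, 0 fell and 8 did not pass (Fasn 40.4 and 32.6, adjusted p = 0.0760), the same adjusted over the list alone. The adipogenic median was -0.080, the mean 0.067 and camera's direction up (adjusted p = 0.978). Without control 2 or 3 that median was 0.001 or -0.023, and without overexpression 1 or 2 it was -0.024 or -0.019.

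Few markers of other cell types could be tested. Of 12 chondrocyte markers, 2 were tested and Sox9 rose from 18.7 to 24.5. Of 12 macrophage markers, 4 were tested and 0 passed. Of 12 skeletal muscle and 10 endothelial markers, 2 and 4 were listed, and 0 of these reached a mean FPKM of 1. The unlisted markers have no values, so their levels are not known here.

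**Figure D3:**
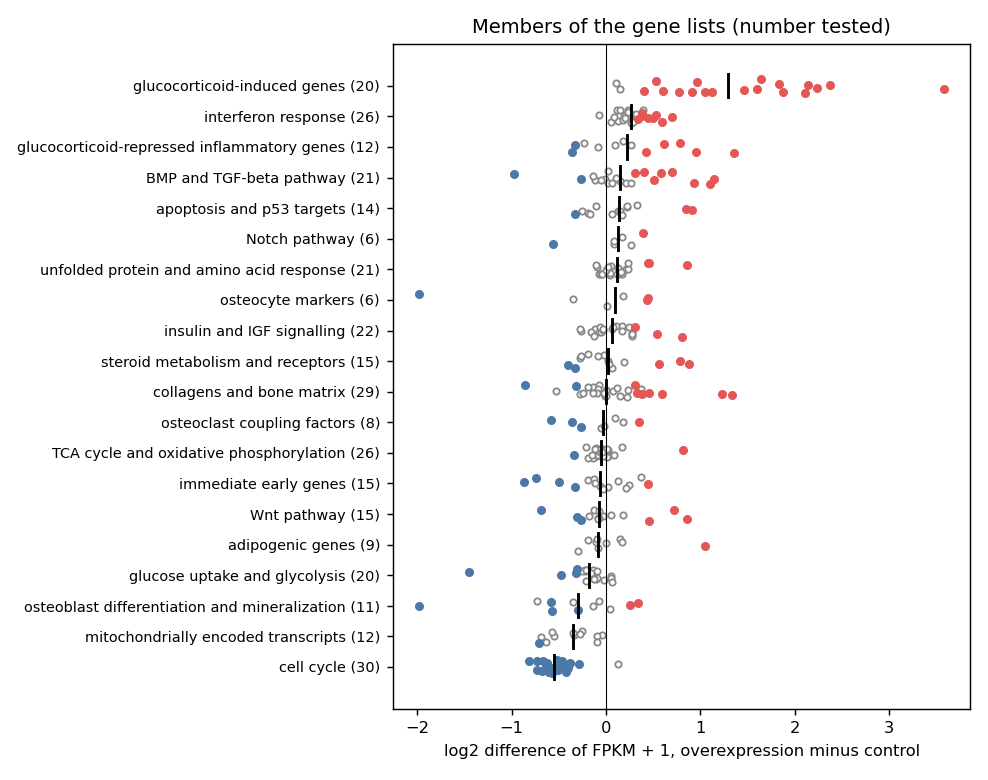
Log2 difference of FPKM + 1 (horizontal axis, overexpression minus control) of the tested members of 20 gene lists, with Hsd11b1 left out as a point; filled red and blue points are higher and lower members past the threshold, open points the others, and black bars list medians over all members. The medians run from -0.547 (cell cycle) to 1.297 (glucocorticoid-induced genes).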

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

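Voom on recovered reads, thinned reads, the fit without the 2 deepest libraries, no filter for the added lists and the steroid list without Hsd11b1 were chosen after the data were seen. Of 123 named genes under the first 3 of these and the settings chosen earlier, 2027 of 2182 values kept direction and side of the threshold, 115 lost the call, 40 gained it and 0 reversed. Of 17 further lists, 324 of 339 values kept theirs, 10 lost and 4 gained the call. Low depth and the FPKM filter limit what can be seen of weakly expressed genes. Where a result below changed, the cause was not tested.

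Without each library in turn, genes higher numbered 483 to 719 and lower 412 to 618. The 2-fold counts were 74 to 84 higher and 11 to 16 lower, Hsd11b1 differed by 7.35 to 7.94, and 5 to 6 further lists passed. Adjusted p spanned 1.58e-30 to 1.11e-25 for glucocorticoid-induced genes, 0.00601 to 0.0267 for osteoblast genes and 0.000299 to 0.0105 for glycolysis genes. The 2-fold counts were 128 higher and 34 lower with a pseudocount of 0.1, 34 and 5 with 5, and voom gave 36 lower. With arrayWeights, 1357 genes were higher, 1403 lower and 19 lower at 2-fold. Without the 2 deepest libraries 478 were lower. With an estimated correlation, adjusted p was 0.230 for osteoblast and 0.403 for glycolysis genes, and 1 of 6 further lists passed. With no filter it was 0.105 for osteoblast genes. Under fry it was 0.0605 for glycolysis genes, and 0.000456 for osteocyte markers, whose direction reversed to lower. Fry also ended the calls of interferon (0.0634), unfolded protein (0.0605) and mitochondrially encoded genes (0.112), and collagen and matrix (0.0152), steroid (0.00544) and p53 genes (0.0108) passed, all in their camera direction. At a mean FPKM of at least 5, unfolded protein genes did not pass (0.0616) and steroid genes did (0.0279). The steroid list holds the transfected Hsd11b1, and without it the list did not pass fry (0.0534) or, at that filter, camera (0.166), but passed fry at that filter (0.00729). Fry does not compare a list with other genes. A block for the replicate number, which the labels do not present as a pairing, called 1316 genes, 1237 of them among the 1582.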

Other observations

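The acute-phase, clock and cholesterol lists, all fits without the 2 deepest libraries, and the identity limit for copies of Gapdh, the test of their reads and the use of the median of all genes were chosen after results had been seen; the splits of the samples and the other tests were set before their own results were seen.

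Acute-phase protein genes, chosen after the top higher genes were seen, numbered 27, of which 10 reached a mean FPKM of 1. Of these 10, 7 rose, 0 fell and 3 did not pass (8 higher adjusted over the list alone). The list was written from these samples, and 5 of the 7 had a control mean under 1 and passed the filter only through the overexpression libraries, so neither count nor camera is independent evidence of direction. With no filter, 14 members were tested, 10 rose and 0 fell. Hp (haptoglobin) went from an FPKM of 0.343 ± 0.098 to 7.31 ± 1.59, Orm1 from 0.083 ± 0.094 to 5.21 ± 0.780, Lbp from 0.922 to 3.64 and C3 from 5.14 to 8.51 (SD, n = 3 per group). Camera over the 3 added lists gave an adjusted p of 2.33e-11, and 0.00352 with an estimated correlation (1.19e-14 and 0.00298 with no filter). Without overexpression 2, the call of Cp ended (adjusted p = 0.0536).

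Cholesterol synthesis genes, which also entered after the results were seen and so are not independent evidence, fell in 14 of 24 members, with 1 higher and 9 not past the threshold (20 lower and 1 higher adjusted over the list alone). Sqle (squalene epoxidase) fell from 40.8 ± 1.39 to 28.4 ± 0.737, Insig1 from 49.5 to 31.5 and Hmgcs1 from 35.1 to 25.2, while Ebp rose from 11.2 to 18.6 (camera adjusted p = 2.33e-11, and 0.00352 with an estimated correlation). Leaving out 1 library gave 10 (without control 3) to 16 lower members, and 11 fell without the 2 deepest. In the clock list, written in the same way, 19 members were tested. Of these, 2 rose, 7 fell and 10 did not pass (3 and 9 adjusted over the list alone). Nfil3 rose from 6.33 to 14.4 and Per1 from 18.8 to 32.7, while Nr1d2 fell from 7.43 to 3.71, Dbp from 1.69 to 0.388 and Per3 from 1.61 to 0.555. The clock list's camera adjusted p was 0.0305, with adjusted p = 0.0822 with an estimated correlation, and 3 members fell without the 2 deepest libraries.

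The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. Each other split mixes libraries of both groups, so the difference between the groups widens its spread and lowers its calls. Low counts in those splits are thus no measure of chance. The real split called 1582 genes and the highest of the others 0 by limma (at unadjusted p under 0.05, 3353 and at most 1375). At a 2-fold change and unadjusted p under 0.05 the real split gave 92 genes and the highest other 7, and camera called 9 lists against 6. For glucocorticoid-induced genes the camera p was 8.44e-30 against 2.64e-06 in the nearest other split, and for osteoblast genes 0.00424 against 0.0616. In each of these, 1 split, the real one, gave the value as large. For glycolysis genes the real p was 0.000319, and 3 splits gave one as small, the smallest 0.000121.

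Control 2 and overexpression 3, the deepest libraries, deviated from their group means together, with a correlation of 0.42 across genes, which are not independent replicates. With all libraries thinned to the shallowest total it was 0.35 (0.33 to 0.36 in 20 further thinnings, 0.40 on the same 11882 genes at full depth), which argues against unequal depth as the whole source. After a cubic in GC content and log2 length was removed from each library, the correlation was 0.17. The plan had named a spline, another kind of smooth curve, in place of the cubic. The value lies between the bounds set for the test, so GC and length may hold part of the correlation and the rest stays open. Deviations followed GC content across genes with r of 0.46 in control 2 and 0.62 in overexpression 3. The other values were -0.47 and 0.07 in control 1 and 3 and -0.37 in both overexpression 1 and 2. Deviations balance out within a group, so opposite signs are partly forced. The difference between the groups also followed GC content, with r of 0.17. The design gives no biological group for this pair, so no biological explanation was tested.

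Gapdh fell by 1.45 on the log2 scale (SE 0.36), beyond the other glycolysis genes. Its 16 listed copies at 98% identity or more held 4.86 times its reads, so reads shared with near-identical copies could affect its level. This met the bound set beforehand for shared reads, that the copies hold at least as many reads as Gapdh. A gain in the copies was required only afterwards. If reads only moved between them, the copies would gain what Gapdh lost. Reads left uncounted because they match several copies were not measured. Gapdh differed by -84.1 CPM (reads scaled to equal library totals, SE 34.5) and the copies by -52.3 CPM (SE 48.4), so no gain was seen, but with this spread, and a log2 difference of the sum of -0.38 (SE 0.19), the test does not decide. Shared reads and a lower Gapdh transcript level with overexpression cannot be told apart here.

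Interferon response genes were higher with overexpression, with a median log2 difference of 0.262. Without the 2 deepest libraries it was 0.402, which argues against the axis shared by that pair as the source. Since the median grew without control 2 and overexpression 3, that pair held less of the rise than the shallower libraries. A difference within the pair alone was not tested. The median of all genes tested was -0.013, which argues against a shift of all genes by scaling. The overexpressed gene itself and a difference between the plasmids or transfections were not tested as explanations and stay open. The list's adjusted p was 0.403 with an estimated correlation and 0.0634 under fry. Without overexpression 2, 1 member was called, without overexpression 1 or control 3, 2, and with arrayWeights 21.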
